A study of Mus musculus with 2 samples.

How the data were processed

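H3K9me3 chromatin immunoprecipitation sequencing of mouse facial prominences at embryonic day 14.5 was deposited as 4 peak lists. Per the labels, the 2 samples were pools of 24 and 34 embryos of both sexes and were separate biological replicates of 1 group, each with 3 technical replicates. Per the file headers of the accompanying descriptions, all lists were in narrowPeak format on mm10. There was 1 list per replicate, 1 called on both replicates together and 1 named replicated, which was derived from the other 3. The aligner, the peak caller, their settings and the rule behind the replicated list were not given in the sources used here. The descriptions named 2 further input files for replicate 2 and for the pooled list, and 1 of these for replicate 1. Their content was not stated, so the background behind the fold values could differ between the replicates.

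Each deposited row gave a score, a fold enrichment (ratio), a −log10 p and a −log10 q per peak, and a summit offset. The score column, deposited by the authors on a scale within each list, was not used. The fold, a ratio deposited by the authors as the enrichment of the peak over its background, was used to describe, rank and filter peaks within a list. The −log10 p and −log10 q values were deposited by the authors and served as a filter and for ranking, and the −log10 p was also compared at matched fold in the closing part. Part of the fold values lay on whole multiples of a single step, namely 50.4% of peaks in replicate 1, 51.0% in replicate 2 and 58.7% in the pooled list (tolerance 0.0002). The steps were 0.284, 0.293 and 0.160. In the deposited lists 74.6% of replicate 1 peaks and 99.2% of replicated peaks had a q-value below 0.05. The smallest −log10 p was 2.01 in replicate 1, 2.03 in replicate 2 and 2.01 in the pooled and replicated lists. No read counts or depths were in the files, so the depth per sample was unknown and no counting interval was given. The number of replicates, 2, limited each SD.

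Every row of the replicated list was identical to a row of the pooled list. The last peak end on each chromosome lay inside the chromosome of the GRCm38 genome used for sequence, which has the coordinates of mm10. Genes came from GENCODE mouse release 21. Peaks were merged within each list. Comparisons used the 19 autosomes and X. Peaks on Y and on scaffolds were counted apart. Permutations moved all intervals of a chromosome by a common random offset, circularly, between its first and last base that is not N, 1000 times with a fixed seed. The alternatives of the sequence measures used 200 shifts.

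A replicate peak was shared when at least 50% of its length was covered by the other list. Peak midpoints were placed in the order promoter (within 1 kb of a start site), exon, intron and intergenic, with protein-coding and lncRNA genes. A gene was overlapped when a replicated peak shared 1 bp or more with its annotated span. The 22 gene lists were compared with all protein-coding genes in 10 strata of gene length by an exact stratified hypergeometric test, two-sided, with Benjamini-Hochberg adjustment over the lists. Such a test treats genes as independent, while neighbours can share a peak. All rotations of a list along the gene order therefore served as an alternative. Gene ends of 2 kb were compared in genes of 4 kb or more by an exact binomial test on genes with a peak at 1 end only. Domains were replicated peaks chained over gaps of up to 10 kb. Soft-masked bases were those written in lower case in the genome, and the masking method was not given in the sources used here. Near-identical copies were found with BLAST 2.17.0 (megablast, word size 16, identity of 80% or more over 300 bp or more, up to 50 targets), among peaks and among the same intervals after 1 shift. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures used matplotlib 3.10.9.

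The tests were tested on simulated data. With marks drawn at the observed rates over 21728 genes, lists of 60 random genes passed an unadjusted p of 0.05 in 2.0% of 100 draws. With the rate doubled (a factor of 2) they passed in 88.0%, and at a factor of 3 in 100.0%. Blocks of 60 neighbouring genes with the observed marks passed in 14.0% of 100 draws by the length-matched test and in 4.0% by rotation. In simulated lists of 20000 intervals with 30% copied, a share of 30.3% was recovered. The copies were exact and the intervals were placed at random. A share near 30% was thus fixed in advance, and this checked only the calculation.

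Named genes followed a rule written before the data were examined. It took up to 4 genes per list with the most covered bases and a peak of each replicate, the 10 genes of 5 kb or more outside the lists with the largest covered share, and the genes in the 10 domains with the most covered bases. A fixed set that includes Peg3, H19, Snrpn, Kcnq1, Dazl, Msx1, Sox9, Actb and Gapdh was added whatever its values. H19 is not protein-coding and was looked up by its annotated span. The members counted at promoters, the families of the 16 placental genes and the genes in families outside the lists were named after their values were seen.

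Alternatives were stricter peaks (−log10 q of 5 or more, or fold of 4 or more), the pooled list, either replicate alone, other overlaps, promoter widths, gene ends and gaps, promoter instead of gene body, and rotation. One more, replicated peaks that touch a peak of each replicate, was added after seeing the data. With 1 group there was no comparison between groups, and no batch was given in the labels.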

Results

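Histone H3 trimethylated at lysine 9 (H3K9me3), a mark of heterochromatin, was mapped by chromatin immunoprecipitation and sequencing in the facial prominences of mouse embryos at embryonic day 14.5. The facial prominences are the tissue swellings from which the face forms. The series held 1 group of 2 biological replicates. Replicate 1 was a pool of tissue from 24 embryos of both sexes and replicate 2 a pool from 34. The labels named no second tissue, stage or treatment, so the design gave a description of this tissue and a comparison between its replicates. The deposited files held peaks, without read counts, and the sequencing depth behind each value was therefore unknown. Replicate 1 had 43137 peaks covering 15.4 Mb and replicate 2 had 53080 peaks covering 16.6 Mb. A list called on both pools together held 80857 peaks. The list the authors deposited as replicated held 25970 of these, covered 16.8 Mb and had a median peak width of 527 bp. All coordinates refer to mm10. Fold enrichment is the value the authors' peak caller gave each peak, and means carry the SD between the replicates.

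The replicates were first compared with each other. Both covered the protocadherin gamma cluster on chromosome 18, where the peaks of each took up 54.4% ± 1.33 (SD, n = 2) of the 180.1-kb span. The zinc finger gene Zfp930 on chromosome 8 was covered over 72.9% ± 1.13 (SD, n = 2) of its length. Of 42861 replicate 1 peaks on the autosomes and X, 14168 (33.1%) had at least 50% of their length under a replicate 2 peak. Among those of fold 4 or more, 61.6% did. Circular shifts of replicate 1 along each chromosome gave a mean of 0.661% ± 0.0629 (SD over 1000 shifts). The observed share was 50.03 times that mean, at a one-sided permutation p of 0.0010, the smallest that 1000 shifts can give. Across the 14168 shared peaks the fold values of the replicates had a Spearman rho of 0.297 and a Pearson r of 0.371 on the log2 scale. These correlations are across peaks, which are not independent replicates, and carry no p. The replicated list kept 97.04% of the pooled peaks in the top decile of fold and 6.06% of those in the lowest. Of its 25970 peaks, 18130 (69.8%) touched a peak of each replicate and 452 touched a peak of neither.

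H3K9me3 peaks were spread unevenly over the chromosomes. Chromosome 7, which carries clusters of vomeronasal receptor and zinc finger genes, had the most covered sequence, with 11931 bp per Mb in the replicated list, 1.85 times the value over all chromosomes. Chromosomes 17 and 13 followed with 1.68 and 1.43 times. Chromosome X had 1070 bp per Mb, or 0.166 times the overall value. In the lists of single replicates X had 1511 ± 162 bp per Mb (SD, n = 2) and chromosome 7 had 10805 ± 407 bp per Mb (SD, n = 2). The lowest autosome, chromosome 14, had 4359 ± 498 bp per Mb (SD, n = 2). Of the pooled peaks on X, 17.3% were kept in the replicated list, against 32.0% over all chromosomes. With 1 group, no test was made of the difference between chromosomes.

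**Figure D1:**
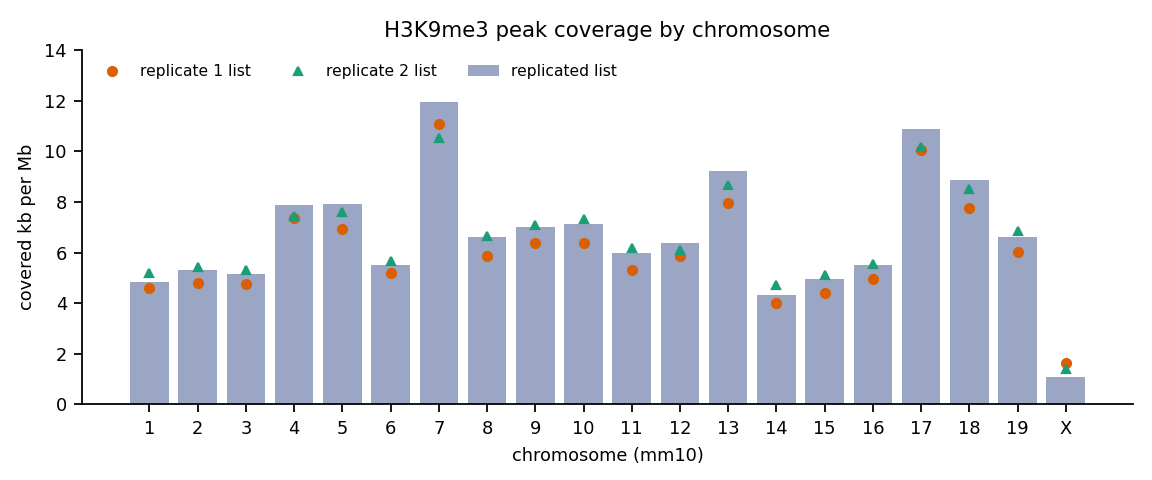
Covered sequence in kb per Mb of each chromosome (x axis, mm10) for the replicated list (bars) and the lists of replicate 1 (circles) and replicate 2 (triangles). Chromosome X has the lowest value in all 3 lists, and chromosome 7 the highest.

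Relative to genes, replicated peaks lay more often in exons and between genes than shifted peaks, and less often in introns and at promoters. Of 25774 peaks, 995 (3.86%) had their midpoint in an exon, 1.26 times the mean of the shifts, and 14601 (56.7%) lay between genes, 1.10 times. Introns held 37.0% (0.879 times) and promoters 2.5% (0.793 times). Each of these 4 differences had a two-sided permutation p of 0.0020, the smallest that 1000 shifts can give, with the same Benjamini-Hochberg adjusted p. Exons of Zfp-named genes held 181 of the exon peaks (18.2%) and exons of clustered protocadherins held 54 (5.43%). The exon ratio without these groups was not computed, so a preference for exons in general was not shown. Among peaks of fold 4 or more the exon ratio was 2.03 (permutation p = 0.0020), and in the pooled list it was 1.03 and did not pass (permutation p = 0.322). Among peaks of fold 4 or more the promoter ratio was 1.00 (permutation p = 0.981), the intergenic ratio 0.976 (permutation p = 0.358) and the intron ratio 0.955 (permutation p = 0.112), so 3 of the 4 differences did not pass among these peaks.

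The sequence under replicated peaks held fewer soft-masked bases than shifted positions. They made up 29.4% of it, against 33.7% ± 0.454 (SD over 1000 shifts). The GC content was 43.5%, against 42.0% ± 0.183 (SD over shifts). Both differences had the smallest two-sided permutation p of 0.0020. The ratio of observed to expected CpG was 0.185, below the 0.194 of the shifts (permutation p = 0.0020), but among peaks of fold 4 or more it was 0.211 and lay above it (permutation p = 0.00995, the smallest that 200 shifts can give). Of the replicated peaks, 417 (1.62%) matched 10 or more others at 80% identity over 300 bp, against 10.5% of shifted intervals. A match to 1 to 9 others was found for 10.3% of peaks and 4.87% of shifted intervals. Shifted intervals can fall where reads cannot be placed uniquely, no mappability track was available, and these differences were not separated from mapping.

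Genes were then compared by 22 lists written before the data were examined. Of 21728 protein-coding genes, 4060 (18.7%) were overlapped by a replicated peak. Zinc finger genes were taken by symbol and are called Zfp-named here. The stem Zfp itself has 394 genes, so some of the 423 genes in the list have other symbols. Many of the 423 encode repressors of transposable elements, and 193 (45.6%) were overlapped. Gene length alone gave an expected 15.0%. The most covered bases were at Zfp943 on chromosome 17 (20 replicated peaks), Zfp981 on chromosome 4 (18 replicated peaks), Zfp933 on chromosome 4 and Zfp930. Peaks of the single replicates covered 15.9% ± 0.764 (SD, n = 2) of Zfp943. They covered 45.1% ± 4.25 (SD, n = 2) of Zfp981 and 52.3% ± 1.94 (SD, n = 2) of Zfp933. The tallest peak in Zfp930 had a fold of 9.52 ± 0.200 (SD, n = 2). Zfp57, a zinc finger gene needed to maintain imprints, had no peak in any of the lists. The Zfp-named list exceeded its expectation 3.04-fold (exact stratified hypergeometric test, Benjamini-Hochberg adjusted over the 22 lists, p = 3.86e-60). Of its 193 genes, 184 were also overlapped by peaks of both replicates. When the list was rotated along the gene order, which keeps neighbours together, the adjusted p was 0.0004.

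**Figure D2:**
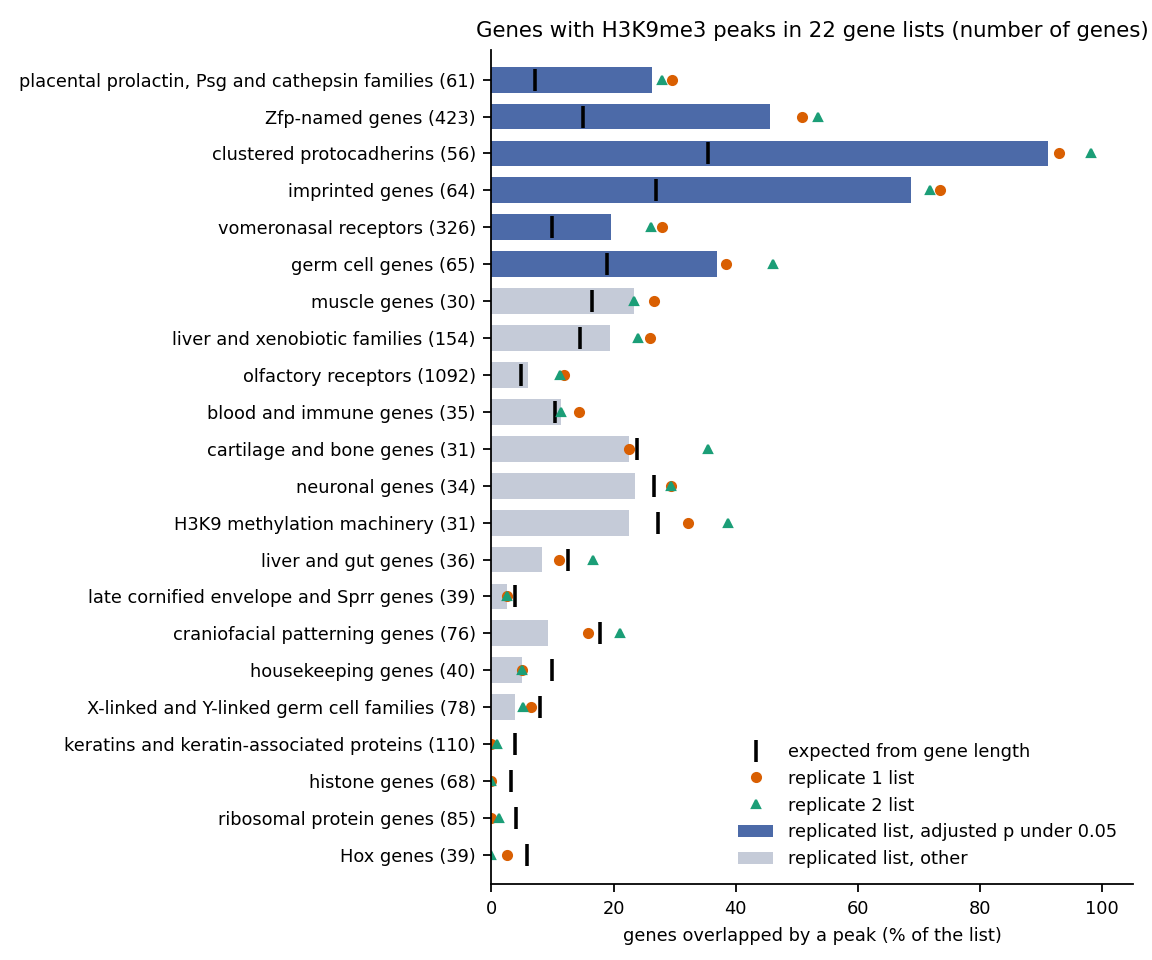
Share of genes overlapped by a peak (x axis, percent) in each of 22 gene lists, with the number of genes in brackets. Bars show the replicated list, dark where the adjusted p is under 0.05, circles and triangles the lists of replicate 1 and replicate 2, and vertical ticks the share expected from gene length. The 6 dark bars lie above their ticks.

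In Zfp-named genes the peaks lay towards the end of the gene. Of 410 such genes of 4 kb or more, 115 (28.0%) had a replicated peak in the last 2 kb and 20 (4.88%) in the first 2 kb. A peak at the last end alone was found in 104 genes and at the first end alone in 9 (exact binomial p = 1.26e-21). Among 18161 other protein-coding genes, 373 (2.05%) had a peak in the last 2 kb and 259 (1.43%) in the first. The preference for the last end was stronger in Zfp-named genes (odds ratio 7.28, Fisher's exact p = 1.74e-11). Both tests treat genes as independent, while neighbouring genes can share a peak, and no rotation was run for them. The ratio of genes with a peak in the last 2 kb to those with 1 in the first was 5.45 in the list of replicate 1 and 6.10 in that of replicate 2, against 5.75 in the replicated list. It was 10.9 among peaks of fold 4 or more.

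**Figure D3:**
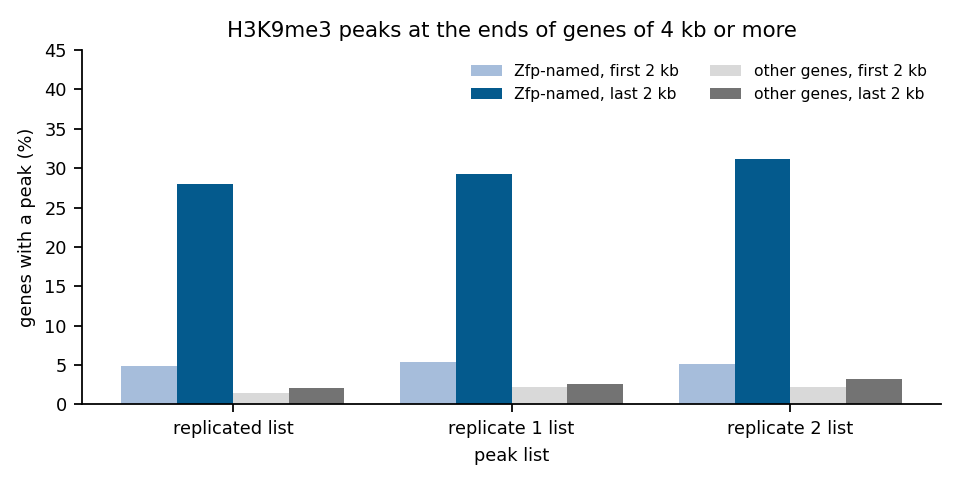
Share of genes of 4 kb or more (y axis, percent) with a peak in the first or last 2 kb, for Zfp-named and other protein-coding genes, in the replicated list and in the lists of replicate 1 and replicate 2 (x axis). In each list the last 2 kb of Zfp-named genes has the tallest bar, 28.0% in the replicated list.

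The clustered protocadherins, cell adhesion genes arranged in 3 arrays on chromosome 18, carried the domain with the most covered sequence in the genome. Replicated peaks overlapped 51 of the 56 genes (91.1%), against 35.4% expected, and reached within 1 kb of the transcription start site of 46. Coverage was highest in the gamma array. Peaks of the single replicates covered 11.3% ± 0.364 (SD, n = 2) of the alpha array at 36930184 to 37187661. The beta array at 37264938 to 37524479 was covered over 22.3% ± 0.850 (SD, n = 2), and the gamma array at 37661793 to 37841873 over 54.4% ± 1.33 (SD, n = 2). Pcdhga1, whose annotated span equals the gamma array, held 43 replicated peaks with a highest fold of 10.95 ± 1.29 (SD, n = 2) in the replicates. The list passed the exact hypergeometric test at an adjusted p of 2.64e-29, and at 0.0014 by rotation, which does not match gene length. The 356 symbol stems with 8 or more genes were searched after the data were seen. Pcdhb had 21 of 22 genes overlapped, against 0.840 expected from gene length (exact test, adjusted p over the stems = 2.30e-27). Pcdhga (12 of 12, against 6.96) and Pcdha (11 of 11, against 7.44) did not pass the exact test (adjusted p = 0.0765 and 0.635). All 3 stems passed by rotation (adjusted p = 0.0455, 0.0443 and 0.0483, exact). Genes of the alpha and gamma arrays share their last exons, so their annotated spans overlap. A peak anywhere in such an overlap counts for several genes. Pcdhga1, Pcdhga2 and Pcdhga3, for example, held 43, 41 and 41 replicated peaks, most of them the same ones.

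**Figure D4:**
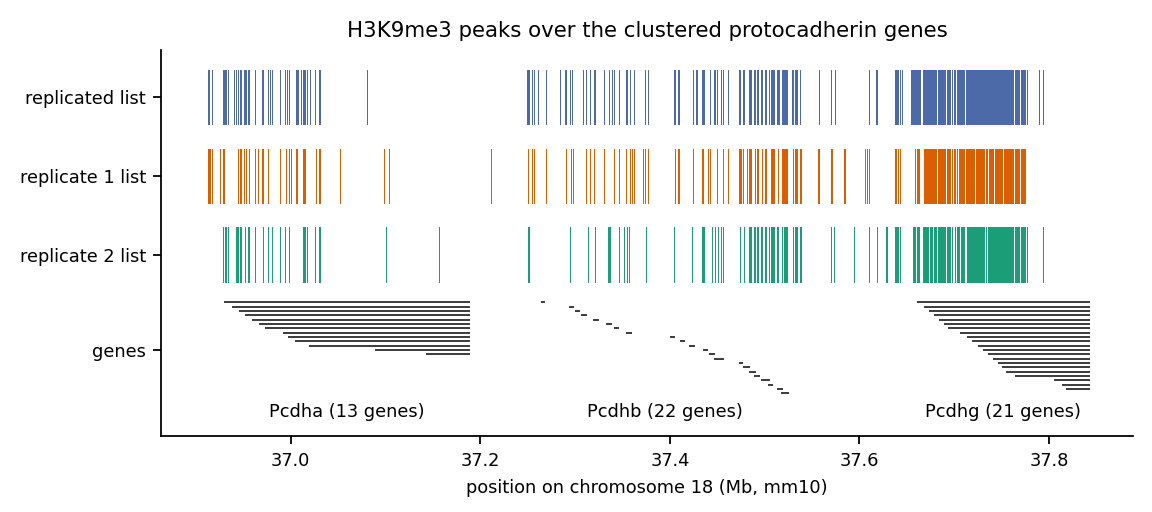
Peaks of the replicated list and of each replicate (coloured blocks) along chromosome 18 (x axis, Mb, mm10), with the spans of the 56 clustered protocadherin genes as black lines. Blocks are densest over the start of the gamma array, where 59.6% of the array's span is covered in the replicated list.

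Imprinted genes, expressed from a single parental copy, were overlapped in 44 of 64 cases (68.8%), against 27.0% expected. Grb10, which encodes a growth-restraining adaptor protein, held 14 replicated peaks on chromosome 11, and its highest fold in the replicates was 7.66 ± 1.19 (SD, n = 2). Gnas on chromosome 2 was covered over 17.2% ± 0.581 (SD, n = 2), and its highest fold was 7.50 ± 0.164 (SD, n = 2). Peg10 was covered over 20.3% ± 2.26 (SD, n = 2), Mest over 24.6% ± 2.04 (SD, n = 2) and Peg3 over 13.1% ± 1.94 (SD, n = 2). Kcnq1, which contains a known imprinting control region, held 17 peaks. Peaks within 1 kb of a start site were found at 15 imprinted genes, including Gnas, Peg10 and Peg3. The body of H19 held no peak, but 2 replicated peaks lay within 5 kb of it, between 142579966 and 142582466 on chromosome 7, upstream of its start site. The list exceeded its expectation 2.54-fold (exact hypergeometric test, adjusted p = 2.73e-15). By rotation, which does not match gene length, the adjusted p was 0.0004.

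Germ cell genes, most of them silent in somatic tissue, were overlapped in 24 of 65 cases (36.9%), against 18.96% expected. Of these, 12 had a peak within 1 kb of the start site, among them Dazl, Ddx4 and Sycp1, which encode an RNA-binding protein, an RNA helicase and a protein of the synaptonemal complex. The highest fold was 5.87 ± 1.65 (SD, n = 2) at Dazl, 4.76 ± 0.10 (SD, n = 2) at Ddx4 and 3.87 ± 1.16 (SD, n = 2) at Sycp1. The list passed at an adjusted p of 0.00089 (exact hypergeometric test) and at 0.0032 by rotation. The call was lost among peaks of fold 4 or more (7 genes, 1.43 times the expectation, exact test, adjusted p = 0.735). It was also lost with a −log10 q of 5 or more and with an overlap of 500 bp or more (13 genes each, exact test, adjusted p = 0.0854 and 0.260). With 10% of the gene body covered, 1 gene remained, 0.844 times the expectation (exact test, adjusted p = 1.00). At the promoter alone, 10.3 times the expected number of genes had a peak (exact test, adjusted p = 1.59e-08).

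Other families that lie in genomic clusters also exceeded the expectation from gene length. Vomeronasal receptors, which detect pheromones, were overlapped in 64 of 326 cases (19.6%), against 9.85% expected (exact hypergeometric test, adjusted p = 1.79e-07). Vmn2r60 on chromosome 7 held 14 peaks. Among the placental prolactin, pregnancy-specific glycoprotein and cathepsin families, 16 of 61 genes (26.2%) were overlapped, against 7.10% expected (exact test, adjusted p = 1.69e-05). These 16 were 7 Ceacam, 7 cathepsin and 2 Psg genes. Ceacam5 held 12 peaks. By rotation along the gene order neither list passed (exact over all rotations, adjusted p = 0.852 and 0.554). Vomeronasal receptors also did not pass with a −log10 q of 5 or more, a fold of 4 or more or the promoter alone (exact test, adjusted p = 0.0854, 0.458 and 0.0673). The placental families did not pass with a fold of 4 or more (exact test, adjusted p = 0.117). Olfactory receptors were overlapped in 65 of 1092 cases (5.95%), against 4.87% expected (exact test, adjusted p = 0.182). In the lists of single replicates more were overlapped, 11.5% ± 0.453 (SD, n = 2), and their excess passed the exact test in each (adjusted p = 4.43e-05 for replicate 2 and 1.27e-09 for replicate 1). Among peaks of fold 4 or more, 6 olfactory receptors were overlapped, 0.327 times the expectation (exact test, adjusted p = 0.0044). By rotation, which does not match gene length, the replicated list had 0.319 times the expected number and passed as lower (exact over all rotations, adjusted p = 0.0004).

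Several lists held no replicated peak, namely 39 Hox genes, 85 ribosomal protein genes, 68 histone genes and 110 keratins and keratin-associated proteins. These genes are short, and their expected counts were 2.29, 3.49, 2.13 and 4.29, so none of these lists passed the exact hypergeometric test (adjusted p = 0.323, 0.131, 0.343 and 0.0671). By rotation, which does not match gene length, all 4 passed as lower (exact over all rotations, adjusted p = 0.0356, 0.0004, 0.0177 and 0.0004). In the list of replicate 1 the ribosomal protein genes and keratins also passed as lower against gene length (exact test, adjusted p = 0.0302 and 0.0111). Keratins did so in the pooled list as well (0 of 110, exact test, adjusted p = 0.00036). Of 76 craniofacial patterning genes, 7 were overlapped (9.21%), against 17.9% expected, which did not pass the exact test (adjusted p = 0.0671). Msx1, Dlx5, Tfap2a and Hoxa2, which encode transcription factors of the face, had no peak in any list. The overlapped genes included Fgfr2, with 24 peaks over an annotated span of 2960900 bp, and Bmp7, Chd7 and Gli3 with 2 peaks each. With a −log10 q of 5 or more, 1 patterning gene was overlapped, 0.121 times the expectation (exact test, adjusted p = 0.0057). This was the only one of 10 alternatives in which the list passed. In the pooled list 20 of the 76 genes were overlapped, 0.847 times the expectation, and in replicates 1 and 2 the ratios were 0.695 and 0.831 (exact test, adjusted p = 0.402, 0.191 and 0.537).

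None of the remaining lists passed the exact hypergeometric test with the replicated list. Cartilage and bone genes were overlapped in 7 of 31 cases, neuronal genes in 8 of 34, muscle genes in 7 of 30 and blood and immune genes in 4 of 35, with ratios to the expectation of 0.948, 0.883, 1.42 and 1.09 and adjusted p from 0.522 to 1.00 (exact hypergeometric tests). Sox9, the regulator of cartilage formation, had no peak, and Col2a1, the cartilage collagen gene, had 1. Sox5 held 11. Ttn, which encodes the muscle protein titin, held 25 replicated peaks, and peaks of the single replicates covered 6.55% ± 1.35 (SD, n = 2) of its length. Of 40 housekeeping genes, 2 were overlapped, 0.504 times the expectation (exact test, adjusted p = 0.611), and Actb and Gapdh had no peak. Liver and gut genes were overlapped in 3 of 36 cases, liver and xenobiotic families in 30 of 154, cornified envelope genes in 1 of 39 and a list of germ cell families found mostly on X and Y in 3 of 78. The ratios were 0.667, 1.34, 0.663 and 0.485. Of the 3 genes in the last list, Magel2 lies on chromosome 7 and is also in the imprinted list. None of these 4 lists passed the exact test (adjusted p from 0.182 to 1.00). With an overlap of 500 bp or more the liver and xenobiotic families passed as higher (26 genes, 1.78 times, exact test, adjusted p = 0.0120), but by rotation they had 1.04 times the expected number (exact over all rotations, adjusted p = 0.887). By rotation the families mostly on X and Y passed as lower (0.206 times, exact over all rotations, adjusted p = 0.0480). This list held no gene on Y, since only the autosomes and X were compared. Rotation moves genes of X over autosomes, so the low coverage of X (0.166 times the overall value) can lower the count by itself. Of 31 genes for H3K9 methylation and its readers, 7 were overlapped (exact test, adjusted p = 0.838), with 12 peaks in Atf7ip and 11 in Lrif1.

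Replicated peaks separated by 10 kb or less were chained into domains. There were 442 domains of 5 or more peaks, which held 18.5% of the peaks. The 4 domains with the most covered sequence were the protocadherin gamma (123 kb), beta (54.9 kb) and alpha (50.1 kb) regions and a stretch on chromosome 13 from 65224545 to 65312257 with Zfp369 and Gm10775 (52.1 kb). The fifth lay in the immunoglobulin heavy chain locus on chromosome 12, from 114249360 to 114464337, with 13 variable gene segments and 49.7 kb covered. There, replicate 1 had 42.6 kb and replicate 2 had 29.3 kb. The next covered the shared end of the Ugt1a genes and Mroh2a on chromosome 1, with 45.1 kb covered over a span of 53.9 kb. A domain on chromosome 4 from 121975125 to 122050558 (40.1 kb) held no protein-coding gene. Others held vomeronasal receptor pseudogenes and the oocyte genes Nlrp4e and Nlrp5 on chromosome 7, and AU041133 on chromosome 10. Outside the lists, the genes of 5 kb or more with the largest covered share were Il3ra on chromosome 14, Asmt on X and Mroh2a. Their coverage was 75.9% ± 10.3, 76.8% ± 5.99 and 71.4% ± 1.07 (SD, n = 2).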

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

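Peaks outside the autosomes and X formed a signal outside the comparisons of chromosomes, genes and sequence, although the shares of pooled peaks kept and of replicated peaks touching each replicate included them. The replicated list held 196 such peaks, 188 on scaffolds and 8 on Y. The lists of replicate 1 and replicate 2 held 276 and 296. Of the 100 pooled peaks with the smallest p, 31 lay there. Several combined a very small p with a modest fold, such as the peak at 62191 to 68645 of the unplaced scaffold JH584304 (fold 4.03, −log10 p 165.9), and the peaks at 3197453 to 3200144 on chromosome 11 (fold 3.76) and 39843008 to 39846813 on chromosome 17 (fold 3.14).

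This comparison was chosen after the values were seen. Of the 100 pooled peaks with the smallest p, 29 had a fold under 5, and 14 of these 29 (48.3%) lay on scaffolds or Y, against 0.349% of all pooled peaks. The −log10 p of the 29 was a median of 7.44 times that of pooled peaks outside the first 100 within 5% of the same fold, but the 29 were picked for a small p, which fixes a high ratio, so this value decides nothing. Sequence present in more copies in the embryos than in the assembly therefore stays open as a candidate explanation, and so does a broad true enrichment. No biological explanation was tested, since the design has 1 group.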

How the results depend on the processing

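Peaks that touch both replicates were added as an alternative after the data were seen, and the other alternatives were set before. The Zfp-named, protocadherin and imprinted lists passed as higher under all 10 alternatives run on them, with ratios of 2.04 to 11.3, 1.88 to 45.3 and 1.70 to 14.9. The excess at the last end of Zfp-named genes passed under all 7 run on it. The share of replicate 1 found in replicate 2 ranged from 17.3% to 61.6% and exceeded the shifts in each setting. The depth was unknown, so what it limits could not be assessed.

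Stricter filters leave fewer peaks, 11038 at a −log10 q of 5 or more and 6351 at a fold of 4 or more. The pooled list held 80857 and the lists without 1 replicate 43137 to 53080. At a −log10 q of 5 or more, the promoter ratio (0.936) and the intergenic ratio (1.02) no longer passed, and CpG turned to 0.202, above the shifts. At a fold of 4 or more, the promoter ratio (1.00) and the intergenic ratio (0.976) crossed 1, the intron ratio (0.955) no longer passed, CpG turned to 0.211, olfactory receptors turned to 0.327 times their expectation, and 80 domains remained of 442. In the pooled list the exon ratio (1.03) no longer passed, there were 2105 domains, and X had 0.261 times the overall coverage. Without 1 replicate X had 0.218 to 0.275 times. A gap of 50 kb gave 842 domains. In peaks that touch both replicates, CpG (0.190) no longer passed. With 10% of the gene body covered, germ cell genes turned to 0.844 times their expectation, on 1 gene. Rotation passed 10 lists, 4 higher and 6 lower, instead of 6 higher, lost the vomeronasal and placental calls, and olfactory receptors turned to 0.319 times. Rotation does not match gene length, which alone can lower families of short genes and raise families of long genes. Under rotation the expected share was 18.7% for each list, while gene length gave 27.0% for imprinted genes and 35.4% for protocadherins. Otherwise the cause was not tested.

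Among 22 lists and 10 alternatives, 195 of 220 values stood on the same side of the threshold, 9 lost a call, 13 gained one and 3 turned. Among these 195 values, 33 had a ratio on the opposite side of 1 from the main result, without a call in either. The covered share of 87 named genes moved by more than the SD between replicates in 305 of 522 values, 61 higher and 244 lower.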

Other observations

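Gene families, in and outside the lists, were searched by the stem of the gene symbol, after the data were seen. Of 356 stems with 8 or more genes, 6 passed the length-matched exact test after Benjamini-Hochberg adjustment, while 19 passed by rotation and 3 by both. Rotation does not match gene length. Stems that passed only by rotation included Cacna, with 10 of 14 genes overlapped against 8.10 expected from gene length. Of the 6, all but the stem Scgb belonged to families in the lists. Zfp, Pcdhb, Vmn and Ceacam passed as higher, while Pcdhga and Pcdha did not pass (adjusted p = 0.0765 and 0.635, exact). By rotation Vmn and Ceacam did not pass (adjusted p = 1.00 and 0.551, exact). The stem Rps, which also takes in genes that are not ribosomal proteins, passed as lower (0 of 44, adjusted p = 0.0496, exact), by rotation too (adjusted p = 0.0131, exact). The sixth was the secretoglobin stem Scgb, with 9 of 34 genes overlapped (adjusted p = 8.02e-05, exact), but not by rotation (adjusted p = 0.989, exact). The Nlrp genes, several of which act in oocytes, were overlapped in 10 of 17 cases, which did not pass against gene length (adjusted p = 0.117, exact) but passed by rotation (adjusted p = 0.0328, exact). The Klra genes, receptors of natural killer cells, had 6 of 11 overlapped (adjusted p = 0.0765, exact, and 0.706 by rotation). The Skint genes had 8 of 11 (adjusted p = 0.457, exact, and 0.255 by rotation).

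The immunoglobulin heavy chain variable segments on chromosome 12 span 2437 kb from 113572927 to 116010093. Peaks of the replicates covered 139.2 kb ± 31.6 (SD, n = 2) of this span, and the replicated list 7.10%. Of 218 variable segments of immunoglobulin genes in the genome, 17 were overlapped and 5.18% of their bases were covered. Of 144 variable segments of T cell receptor genes, 1 was overlapped and 0.596% of the bases were covered. Over protein-coding genes 0.798% of the bases were covered. These groups were chosen after the values were seen.

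The copy number test of X and the last-exon test of Zfp-named genes were chosen after a result was seen, and the other tests of these 2 patterns before. Chromosome X had 0.299 times the autosomal number of pooled peaks per Mb. In windows of 100 kb matched on soft-masked share it still had 0.245 times. By bin of soft-masked share the ratio fell unevenly, from 0.411 at 20 to 25% to 0.189 at 65 to 70%. It was 0.0131 at 70 to 75%, on 27 windows of X. The matched ratio argues against the soft-masked share alone as the whole cause. Repeat families and mappability on X were not tested and could still contribute. For replicated peaks the ratio was 0.160, and 0.156 away from Zfp-named and protocadherin genes. This argues against few such genes as the whole cause. Pools of both sexes hold fewer copies of X than of autosomes, 0.75 times if the sexes are equal in number, which the labels do not state, and then an X peak of fold f over a fixed background could match an autosomal peak of f divided by 0.75. Peaks per Mb compared in this way had a median ratio of 0.919 over 5 values of f (0.723 to 1.19). Single autosomes treated as X was had 3.38 to 10.7, but the higher cut on the other autosomes raises these values by itself. At the same fold the median ratio was 0.190 for X and 0.680 to 1.73 for single autosomes. The gap on X thus had about the size that this copy number could give. Any other cause of that size would give the same ratio, and the background behind the fold values was not stated. Lower copy number therefore stays open and was not decided by this comparison. A lower level of the mark on X stays open, and no biological explanation was tested, since the design has 1 group.

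Peaks at the last 2 kb of Zfp-named genes were set against shared reads and long last exons. Replicated peaks with a near-identical copy under another replicated peak were left out. Then 80 Zfp-named genes had a peak at the last end only and 12 at the first end only (exact binomial p = 1.72e-13). This argues against reads shared between copies that both carry a replicated peak as the whole cause. Copies elsewhere in the genome were not searched, so reads shared with those were not tested. Among genes with a last exon of 2 kb or more, 76 Zfp-named genes had a peak at the last end only and 5 at the first only, while of the others 136 had it at the last end only and 67 at the first only, which is 0.134 times the preference of Zfp-named genes (Fisher's exact p = 7.15e-07) and argues against long last exons as the whole cause. More distant copies, GC content and mappability were not tested and could still contribute. These tests of gene ends also treat neighbouring genes as independent. No biological explanation was tested, since the design has 1 group.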
